A study of Rattus norvegicus with 4 samples.

How the data were processed

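The samples were 4 droplet libraries of wild-type rats, 2 of skin and 2 of subcutaneous fascia. The deposited values are UMI counts per gene and cell barcode. Per the submitters' processing notes, the authors aligned the reads with STAR within Cell Ranger 6.0.1, while the matrix header names Cell Ranger 7.0.0. The notes name the rat build mRatBN7.2 beside the human build GRCh38.p13. Whether reads in introns were counted is not stated. The table has 30560 genes, of which 7162 carry only an identifier, and the annotation table supplied gives no identifiers that match these, so only genes with a symbol are named.

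Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublets were marked with Scrublet as built into Scanpy 1.11.5. Where it marked under 0.5% of a library, as in both skin libraries, the top-scoring share of 0.8% per 1000 cells was removed instead. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components gave a graph of 15 neighbours, and Leiden clustering (leidenalg) at resolution 1.0 gave 38 clusters. Each cluster was named from markers fixed before the data were examined, 220 of 242 of which matched, by the mean, over a class's markers, of the log2 ratio of the cluster's CPM to the mean CPM of all clusters. A name required 3 detected markers and a score of at least 0.5. With a gap under 0.3 to the next class, it also required more markers among the 10 leading genes, which named the lymphatic and neutrophil clusters. A cluster with a class of another lineage at 1.0 or more, within 1.5 of the first, counted as mixed. Mixed clusters stayed unnamed, as did those led by another class's markers or with few UMIs and no leading marker. Endothelial, myeloid and lymphoid classes each counted as 1 lineage. Unnamed cells count in the totals behind the shares.

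Counts were summed per library over all cells and over each class with at least 20 cells in every library. They were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Class shares were compared with the same test on numbers of cells. The SE of a log2 change was derived from its test statistic. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and with an estimated one, and with fry, and counts within a list were adjusted over its genes alone. Cd34 shares and the split by Cd34 used cells of at least 2000 UMIs thinned to that number. Intervals of shares are exact at 95%. A gene without UMIs in a tissue was set to 3 counts over the group, and ratios with 1 to 3 counts have a counting interval. On simulated changes of 4-fold, the test found 65% of genes in all cells, 78% in fibroblasts, 79% in blood endothelial cells, 73% in mural cells, 54% in macrophages, 76% in lymphocytes and 76.5% in dendritic cells, and of 2-fold changes 1.5%, 4.5%, 17%, 22%, 3%, 16% and 0%.

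The genes named were, by a rule fixed before the data were examined, the 12 called genes with the largest change in each direction in fibroblasts, 5 in other classes and 8 in all cells and in the Cd34 split. They needed at least 20 CPM in the higher tissue, libraries that did not overlap between tissues, a symbol, and, within a class, 0.2 or more of the level in the class where the gene is highest. Added were 2 or 3 members of the called lists, and Cd34, Pdgfra, Pi16, Dpp4, Cd55, Col1a1, Col3a1, Thy1 and Pecam1 in fibroblasts. Lists with at least 3 called members but no camera call have members named in fibroblasts only, which departs from the rule, and dendritic cells have only their count, 1 list and Cd34. Some genes that the rule selects are not reported here. The haemoglobin and muscle lists had under 5 tested genes and were not tested as sets.

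The alternatives were DESeq2 1.42.0, size factors by relative log expression, no low-count filter, replicate number as a block, each library left out, other minimums of genes and mitochondrial UMIs, doublets kept, Leiden resolution 0.5 and 2.0, limma on logit shares, other depths for thinning, and genes under 0.2 of the highest class left out. Added after the data were seen were keratinocytes left out of the total of the shares, mixed clusters named by their best class, 1 shared cluster alone, free-RNA genes left out of the lists, and each cluster of each library as a block of the Cd34 split. Where a tissue kept 1 library, its spread was taken from the other tissue.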

Results

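Single-cell RNA sequencing (10x Genomics) was performed on wild-type rat skin and subcutaneous fascia (2 libraries each). Each library is a table of UMI counts, that is, of distinct RNA molecules per gene and cell barcode. The deposited barcodes numbered 7945 and 17527 in skin replicates 1 and 2 and 7697 and 7712 in fascia replicates 1 and 2, and held 88334062, 85165728, 95777810 and 83852172 UMIs in the same order. After filtering, 7058, 14215, 6604 and 6805 cells were kept in the same order. Their median depth was 8891 and 2489 UMIs per cell in skin and 12678.5 and 10322 in fascia. Skin replicate 2 was the shallowest, with 41.4% of its kept cells under 2000 UMIs. The labels do not say whether the libraries come from different animals, so edgeR's p-values measure the spread between libraries. Those of the Cd34 split use within-library differences, and camera's compare a list with other genes. A two-sided exact permutation test of 2 against 2 cannot give a p under 0.33, so models share the spread across genes or classes. Levels are in CPM, UMIs scaled to a common total of UMIs per class and library. Log2 changes are fascia relative to skin, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg correction unless said otherwise. A gene is called at an adjusted p under 0.05.

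The first comparison asked how the make-up of the fascia differs from that of the skin. Keratinocyte-like cells, the epithelium of the epidermis and hair follicles, were 81.8% (80.9 to 82.7) and 60.3% (59.5 to 61.1) of skin cells and 0.076% (0.025 to 0.177) and 0.118% (0.051 to 0.232) of fascia cells. The ranges are exact 95% binomial intervals that cover counting error only. Their log2 share ratio was -9.50 (SE 1.37, adjusted p = 6.07e-06), and -6.38 with at least 200 genes per cell and -11.80 at Leiden resolution 0.5, both called. Keratinocytes fill most of the skin total, which by itself raises the ratios of the other classes. Fibroblast-like cells were 4.55% (4.07 to 5.06) and 3.02% (2.74 to 3.31) of skin cells and 38.8% (37.6 to 40) and 10.6% (9.89 to 11.4) of fascia cells. Mural-like cells, the pericytes and smooth muscle of vessel walls, were 1.09% (0.862 to 1.36) and 1.97% (1.75 to 2.21) of skin cells and 19.1% (18.1 to 20) and 28.6% (27.5 to 29.7) of fascia cells. Macrophage- or monocyte-like cells were 0.638% (0.465 to 0.852) and 0.204% (0.137 to 0.293) of skin cells and 21.3% (20.3 to 22.3) and 20.4% (19.5 to 21.4) of fascia cells. Blood endothelial-like cells were 2.08% (1.76 to 2.44) and 3.21% (2.93 to 3.52) of skin cells and 9.3% (8.61 to 10) and 15.8% (15 to 16.7) of fascia cells. T- or NK-like lymphocytes were 1.25% (1 to 1.53) and 1.01% (0.849 to 1.18) of skin cells and 4.74% (4.24 to 5.28) and 11.4% (10.7 to 12.2) of fascia cells.

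The log2 share ratios were 5.64 (SE 1.14, adjusted p = 0.000227) for macrophages or monocytes, 3.96 (SE 1.05, adjusted p = 0.00196) for mural cells, 2.84 (SE 1.0, adjusted p = 0.0151) for lymphocytes, 2.71 (SE 0.99, adjusted p = 0.0151) for fibroblasts and 2.24 (SE 0.98, adjusted p = 0.0346) for blood endothelial cells. Neutrophil-like cells (4.32, SE 1.12, adjusted p = 0.00194) and B- or plasma-like cells (3.11, SE 1.13, adjusted p = 0.0151) were also higher in fascia. Numbers of cells in skin and fascia were 1 and 10 against 17 and 111 neutrophils and 2 and 5 against 16 and 23 B cells. Lymphatic endothelial-like cells, led by the chemokine gene Ccl21, were 1.32% (1.06 to 1.61) and 3.7% (3.4 to 4.02) of skin cells and 1 cell in each fascia library. Their log2 ratio was -7.26 (SE 1.35, adjusted p = 0.00012). Mast-like cells numbered 67 and 31 in skin and 2 and 0 of 6805 in fascia, where a count of 0 allows a share of up to 0.0441%. The log2 ratio of mast cells was -5.14 (SE 1.30, adjusted p = 0.00182). At Leiden resolution 2.0 the B cell ratio turned to -0.81, not called. The share of dendritic-like cells was not called, with 1.57 (SE 0.96, adjusted p = 0.114). Of 11 classes, 10 were called, against 3 without skin replicate 1 and as many without skin replicate 2, 6 without fascia replicate 2 and 8 without fascia replicate 1. The fibroblast ratio was 1.49 without fascia replicate 1, which holds most fascia fibroblasts. Calls were lost without skin replicate 1 and without skin replicate 2 for fibroblasts, blood endothelial cells, mural cells, lymphocytes, B cells, mast cells and neutrophils. They were lost without fascia replicate 2 for blood endothelial cells, lymphocytes, B cells and neutrophils, and without fascia replicate 1 for fibroblasts and blood endothelial cells.

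With keratinocytes left out of the total, as tried after the data were seen, only lymphatic endothelial cells were called, at -8.90 (adjusted p = 0.0031). Macrophages were then 3.51% and 0.514% in skin and 21.3% and 20.5% in fascia, and mural cells 6% and 4.96% in skin and 19.1% and 28.6% in fascia. Their ratios of 3.40 and 2.12 each had an adjusted p = 0.084. Fibroblasts were 25% and 7.6% in skin and 38.8% and 10.6% in fascia, blood endothelial cells 11.5% and 8.1% in skin and 9.3% and 15.8% in fascia and lymphocytes 6.86% and 2.53% in skin and 4.74% and 11.4% in fascia, with ratios of 0.60, 0.36 and 0.79. B cells were at 1.34, neutrophils at 2.74, mast cells at -7.35 and dendritic cells turned to -0.78. This total still holds the unnamed cells, 3670 of 5643 in skin replicate 2.

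Cells of 6 of the 38 clusters were left unnamed, 3.05% (2.66 to 3.47) and 25.8% (25.1 to 26.5) in skin and 3.68% (3.24 to 4.16) and 2.69% (2.32 to 3.1) in fascia. Most of them were in skin replicate 2, in 2 clusters with fibroblast and keratinocyte markers (1756 and 783 cells of that library) and 1 with mural and keratinocyte markers (1130 cells). Named by their best class, as tried after the data were seen, these clusters moved the fibroblast log2 share ratio to 0.80, the mural one to 2.11 and the blood endothelial one to 2.27, none of which was called. With Leiden resolution 0.5 and 2.0 the fibroblast ratio was 1.90 and 2.46, neither called.

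**Figure D1:**
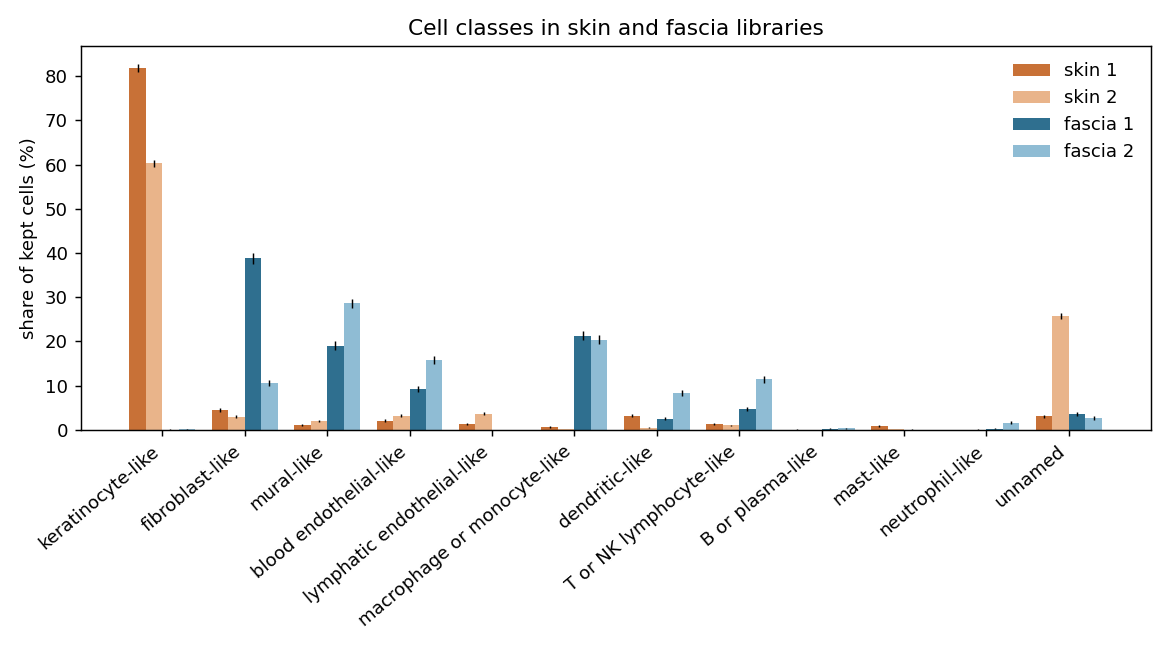
Share of kept cells (%) in each cell class, with 1 bar per library and exact 95% binomial intervals. Keratinocyte-like cells hold 81.8% and 60.3% of the skin libraries, and macrophage-like cells 21.3% and 20.4% of the fascia libraries.

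Counts summed over all kept cells gave a view of each tissue that mixes its make-up with expression. The fascia carried high levels of macrophage genes, with Fcna, a ficolin of tissue macrophages, at log2 7.50 (SE 0.56, adjusted p = 0.0038) and the haemoglobin scavenger receptor gene Cd163 at 6.86 (SE 0.44, adjusted p = 0.0032). Ccr2, the chemokine receptor of inflammatory monocytes, reached 7.70 (SE 1.14, adjusted p = 0.011). The fibroblast genes Pi16 at 6.78 (SE 1.42, adjusted p = 0.023) and Wnt2, a secreted Wnt ligand, at 7.38 (SE 1.05, adjusted p = 0.01) were higher too, as were Pmfbp1 at 6.95 (SE 0.46, adjusted p = 0.0034) and Hbb-b1, a haemoglobin beta chain, at 8.45 (SE 0.86, adjusted p = 0.0057). Mrgprg, an orphan Mas-related receptor, had 0 and 0.0131 CPM in skin and 212 and 12.3 CPM in fascia, a ratio of 18700 (counting interval 3360 to 739000). Genes of epidermal differentiation and hair led the other direction. Among them, Fgfbp1 at 171 and 293 CPM in skin was at least 12800-fold lower in fascia, where it had no UMI, taking 3 counts over the group as the floor. The cornified envelope gene Lce1m (at least 3210-fold), the protease inhibitor genes Spink5 (at least 2620-fold) and Serpina11 (at least 2470-fold) and the hair keratin gene Krt33b (at least 2130-fold) had no UMI in fascia either. Ly6d, Sprr1a and Mt4 had 1 or 2 UMIs in fascia, with ratios of skin to fascia of 125000 (counting interval 34600 to 1030000), 81500 (counting interval 14600 to 3220000) and 31900 (counting interval 5720 to 1260000). Cd34 was at 11 and 7.82 CPM in skin and 56.9 and 25 CPM in fascia, a log2 change of 1.90 (SE 0.49, adjusted p = 0.038).

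In the summed counts, 3399 genes were higher and 3350 lower in fascia of 17817 tested. The count of 6749 was 2947 and 3710 without skin replicates 1 and 2, and 3535 and 4477 without fascia replicates 1 and 2. Without skin replicate 1, the calls were lost for Pi16, Wnt2, Mrgprg and Cd34. With skin replicate 2 left out, the calls were lost for Pi16, Wnt2, Mrgprg and Cd34. Without fascia replicate 1, the call was lost for Cd34 (1.13).

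The next comparison asked how fibroblast-like cells of the fascia differ from those of the skin. Fascia fibroblasts expressed Daglb, which makes the endocannabinoid 2-arachidonoylglycerol, at 1420 and 809 CPM against 4.42 and 9.06 in skin, a log2 change of 7.07 (SE 0.50, adjusted p = 0.012). They were also higher in Efhd1, a mitochondrial calcium-binding protein gene, at 7.26 (SE 0.88, adjusted p = 0.019) and in Dact2, a modulator of Wnt signalling, at 6.92 (SE 0.73, adjusted p = 0.017). The same direction was seen in the retinoic acid synthesis gene Aldh1a3 at 6.91 (SE 0.73, adjusted p = 0.018) and the hydrogen peroxide-making oxidase gene Duox1 at 6.62 (SE 0.76, adjusted p = 0.019). Skin fibroblasts expressed Igfbp2, an insulin-like growth factor-binding protein gene, at 4160 and 2140 CPM, where fascia had 0.407 and 0.346, a log2 change of -13.39 (SE 0.82, adjusted p = 0.012). The matrix protease gene Mmp3 (-10.77, SE 0.77, adjusted p = 0.012), the coagulation factor gene F5 (-10.16, SE 0.83, adjusted p = 0.012) and Ccl19, a chemokine that attracts lymphocytes and dendritic cells, (-9.66, SE 0.85, adjusted p = 0.014) were lower in fascia.

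Genes nearly limited to 1 tissue's fibroblasts have a ratio of CPM in place of a log2 change. Pkd1l2, of the polycystin family, had no UMI in skin and was at least 52.9-fold higher in fascia. The receptor gene Mrgprg (2600, counting interval 467 to 103000), the sulfotransferase gene Chst1 (426, counting interval 76.4 to 16800), the homeobox gene Gsc (298, counting interval 53.4 to 11800), Shisa6 (199, counting interval 35.7 to 7870) and Nell1 (216, counting interval 74 to 1050) had 1 to 3 UMIs in skin. On the skin side, Tmem132c (1210, counting interval 333 to 10100), Arhgef19 (1150, counting interval 203 to 45600) and Gldn (901, counting interval 306 to 4390) had 1 to 3 UMIs in fascia. Thbs1, which codes for thrombospondin-1, an activator of TGF-beta, was lower at -8.52 (SE 1.21, adjusted p = 0.025), as were Ndufa4l2 at -8.98 (SE 1.06, adjusted p = 0.019) and Hs6st3, a heparan sulfate sulfotransferase gene, at -8.55 (SE 0.53, adjusted p = 0.012). The growth factor receptor gene Fgfr4 (-8.80, SE 0.60, adjusted p = 0.012) and the keratin gene Krt76 (-8.72, SE 0.59, adjusted p = 0.012) completed the 12 in that direction. Hbb-b1 rose by 8.19 (SE 0.32, adjusted p = 0.0099), and 1% of fascia fibroblasts held 73.3% and 55.5% of the haemoglobin UMIs.

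Among the genes fixed for their part in fibroblast identity, Dpp4 at 4.43 (SE 0.50, adjusted p = 0.019) and Cd55 at 2.91 (SE 0.44, adjusted p = 0.028), both markers of adventitial fibroblasts, were higher in fascia. Pi16, another such marker, was at 5.12 and 193 CPM in skin and 4180 and 1620 CPM in fascia and was not called (4.67, SE 1.58, adjusted p = 0.13). The collagen genes Col1a1 (-2.70, SE 0.74, adjusted p = 0.085) and Col3a1 (-1.52, SE 0.59, adjusted p = 0.16) were not called, nor were Pdgfra (0.55, SE 0.20, adjusted p = 0.14), Thy1 (-0.01, SE 0.25, adjusted p = 0.98) and the endothelial gene Pecam1 (0.62, SE 0.68, adjusted p = 0.58). Of these, Pi16 was 8.59 without skin replicate 2, and Col1a1 and Col3a1 were -1.67 and -0.74 without skin replicate 1. Thy1 was between -0.31 and 0.25 and Pecam1 between -0.14 and 1.31, the low ends without fascia replicate 2 and the high ends without fascia replicate 1 for Thy1 and without skin replicate 2 for Pecam1.

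Of 12407 genes tested in fibroblasts, 402 were higher and 916 lower in fascia. Mostly different clusters held the class in each tissue. Cluster 23, led by Igfbp2, Col1a1, Lum and Ccl19, held 97.2% and 35.7% of skin fibroblasts, and cluster 2, led by Pi16, Daglb and Mrgprg, held 74.1% and 61.5% of fascia fibroblasts. Cluster 11 held 63.9% of skin replicate 2 but 2.8% of skin replicate 1, and 23% and 30.6% of fascia. No gene passed without fascia replicate 1 or without fascia replicate 2. At an unadjusted p under 0.05 there were 1695 and 2214 such genes without them, while DESeq2 on all libraries called 2239 and edgeR without skin replicate 2 called 2633.

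Gene lists fixed before the data were examined group these changes. The adventitial fibroblast list had 10 higher, 1 lower and 9 not called of 20 tested (14 and 1 within the list), camera adjusted p = 3.14e-09, or 0.54 with an estimated correlation. Efhd1, Dact2, Wnt2 at 5.12 (SE 0.42, adjusted p = 0.012) and Dpp4 were among its higher members. The upper dermis and dermal papilla list had 1 higher, 13 lower and 4 not called of 18 tested (2 and 13 within the list), camera adjusted p = 2.73e-07, or 0.54 with an estimated correlation. Col13a1, a transmembrane collagen gene, was at -6.82 (SE 0.56, adjusted p = 0.012), and Tfap2c had 2 UMIs in fascia and a ratio of 112 (counting interval 28.3 to 965). The Wnt modulator and target list had 2 higher, 9 lower and 7 not called of 18 tested (4 and 9 within the list), camera adjusted p = 0.129, or 0.54 with an estimated correlation. Wnt10b rose, with 1 UMI in skin and a ratio of 161 (counting interval 28.9 to 6380), and Wnt2 rose too. The tendon and ligament list had 0 higher, 4 lower and 4 not called of 8 tested (0 and 4 within the list), camera adjusted p = 0.000189, or 0.54 with an estimated correlation. Mkx, a tendon transcription factor gene, had no UMI in fascia and was at least 43.4-fold lower, and Tnc, the matrix protein tenascin-C, was at -5.69 (SE 1.01, adjusted p = 0.037). The TGF-beta response and myofibroblast list had 0 higher, 6 lower and 13 not called of 19 tested (0 and 7 within the list), camera adjusted p = 0.0044, or 0.54 with an estimated correlation. Inhba, an activin subunit gene, was at -7.31 (SE 0.33, adjusted p = 0.01), beside Thbs1.

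Matrix genes moved both ways. The fibrillar collagen and collagen processing list had 1 higher, 1 lower and 21 not called of 23 tested (1 and 1 within the list), camera adjusted p = 0.0104, or 0.641 with an estimated correlation. Its called members were both lysyl oxidase genes, which crosslink collagen: Lox at -2.58 (SE 0.46, adjusted p = 0.037) and Loxl1 at 1.85 (SE 0.34, adjusted p = 0.04). The elastic fibre list had 2 higher, 4 lower and 10 not called of 16 tested (4 and 4 within the list), camera adjusted p = 0.752, or 0.881 with an estimated correlation. Fbn2, a fibrillin gene, was at -3.48 (SE 0.47, adjusted p = 0.022) and Mfap4 at -3.03 (SE 0.54, adjusted p = 0.037). The proteoglycan and hyaluronan list had 0 higher, 4 lower and 11 not called of 15 tested (2 and 4 within the list), camera adjusted p = 0.0768, or 0.54 with an estimated correlation. Tnfaip6, a hyaluronan-binding protein gene, was at -3.66 (SE 0.65, adjusted p = 0.037), and Cd44, the hyaluronan receptor gene, at -3.42 (SE 0.65, adjusted p = 0.041). Other matrix and lineage lists without a camera call were basement membrane (0 higher, 1 lower of 17, camera adjusted p = 0.881), lower dermis (1 higher, 1 lower of 13, camera adjusted p = 0.897), adipogenic (1 higher, 2 lower of 11, camera adjusted p = 0.752) and positional transcription factor (1 higher, 2 lower of 27, camera adjusted p = 0.897). In the adipogenic list Pparg was at 4.11 (SE 0.49, adjusted p = 0.019) and Icam1 at -3.89 (SE 0.30, adjusted p = 0.012). In the positional list Meox2 was at -2.07 (SE 0.29, adjusted p = 0.024) and Irx3 at -1.39 (SE 0.24, adjusted p = 0.035).

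Several stress-response and inflammatory genes were lower in fascia fibroblasts. The immediate early and heat shock list had 0 higher, 14 lower and 8 not called of 22 tested (0 and 19 within the list), camera adjusted p = 3.46e-14, or 0.54 with an estimated correlation. The small heat shock protein gene Hspb1 was at -4.21 (SE 0.77, adjusted p = 0.038) and the stress transcription factor gene Atf3 at -3.86 (SE 0.59, adjusted p = 0.028). The cytokine and chemokine list had 0 higher, 9 lower and 13 not called of 22 tested (2 and 12 within the list), camera adjusted p = 1.4e-06, or 0.54 with an estimated correlation. Cxcl3, a neutrophil chemokine, was at -7.42 (SE 0.46, adjusted p = 0.012), beside Ccl19. The hypoxia and glycolysis list had 0 higher, 2 lower and 12 not called of 14 tested (0 and 5 within the list), camera adjusted p = 0.00526, or 0.54 with an estimated correlation. Ankrd37 was at -2.55 (SE 0.40, adjusted p = 0.03) and the glucose transporter gene Slc2a1 at -2.49 (SE 0.36, adjusted p = 0.026). The angiogenic and growth factor list had 1 higher, 7 lower and 13 not called of 21 tested (4 and 9 within the list), camera adjusted p = 0.0209, or 0.637 with an estimated correlation. Bmp7 was at 4.86 (SE 0.78, adjusted p = 0.031) and Nrg1, an ErbB ligand gene, at -4.65 (SE 0.69, adjusted p = 0.027). The axon guidance and neurotrophin list had 1 higher, 4 lower and 12 not called of 17 tested (3 and 6 within the list), camera adjusted p = 0.022, or 0.54 with an estimated correlation. The semaphorin genes Sema3e and Sema3a were at -5.97 (SE 0.47, adjusted p = 0.012) and -4.86 (SE 0.98, adjusted p = 0.046). In fibroblasts the 13 epidermal transcripts made up 0.043% and 0.158% of UMIs in skin replicates 1 and 2 against 0.001% and 0.002% in fascia.

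Markers of other cell types moved with the tissues as well. The epidermal transcript list had 0 higher, 12 lower and 1 not called of 13 tested (0 and 12 within the list), camera adjusted p = 9.05e-25, or 0.54 with an estimated correlation. Its 13 members all had a CPM under 0.2 of that in keratinocytes, and Krt5 and Krt17 had no UMI in fascia fibroblasts (at least 1810-fold and 1620-fold lower). The MHC class II list had 2 higher, 0 lower and 3 not called of 5 tested (5 and 0 within the list), camera adjusted p = 0.000703, or 0.54 with an estimated correlation. Its 5 members were under 0.2 of the level in the highest class, with Cd74 at 3.77 (SE 0.53, adjusted p = 0.024) and RT1-Da at 2.66 (SE 0.52, adjusted p = 0.044). The resident macrophage list had 2 higher, 2 lower and 7 not called of 11 tested (4 and 2 within the list), camera adjusted p = 0.0958, or 0.664 with an estimated correlation. Ccl24 and Lyve1 had no UMI in skin fibroblasts (at least 11.8-fold and 6.79-fold higher in fascia), at 3.47 and 6.4 and 2.66 and 3.03 CPM in fascia. Lists without a camera call were proliferation (0 higher, 1 lower of 15, camera adjusted p = 0.752), complement (1 higher, 1 lower of 12, camera adjusted p = 0.234), interferon response (2 higher, 2 lower of 14, camera adjusted p = 0.864), inflammatory monocyte (0 higher, 1 lower of 8, camera adjusted p = 0.897), lipid-associated macrophage (0 higher, 1 lower of 10, camera adjusted p = 0.77) and endothelial subtype (0 higher, 2 lower of 9, camera adjusted p = 0.202). Of the interferon list, Oas1a was at 3.98 (SE 0.83, adjusted p = 0.05) and Cxcl10 at -3.75 (SE 0.75, adjusted p = 0.045). The median, mean and test differed in sign for the elastic fibre, adipogenic and inflammatory monocyte lists.

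Every call for a single fibroblast gene was lost without either fascia library. Without skin replicate 1, the calls were lost for Mrgprg, Chst1, Nell1, Wnt10b, Tnc, Lox, Loxl1, Fbn2, Mfap4, Tnfaip6, Cd44, Irx3, Ankrd37, Sema3a, Cd74, RT1-Da, Ccl24, Lyve1 and Oas1a, and Cxcl10 moved to -2.27. With skin replicate 2 left out, the calls were lost for Chst1 (adjusted p = 0.075), Nell1 and RT1-Da. Of the called lists, fibrillar collagens had an adjusted p = 0.06 by limma's camera without skin replicate 1. When skin replicate 2 was left out, camera gave 0.21 for the tendon, 0.21 for the TGF-beta, 0.83 for the angiogenic and 0.2 for the axon guidance list, and for the angiogenic list 0.081 without fascia replicate 1.

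**Figure D2:**
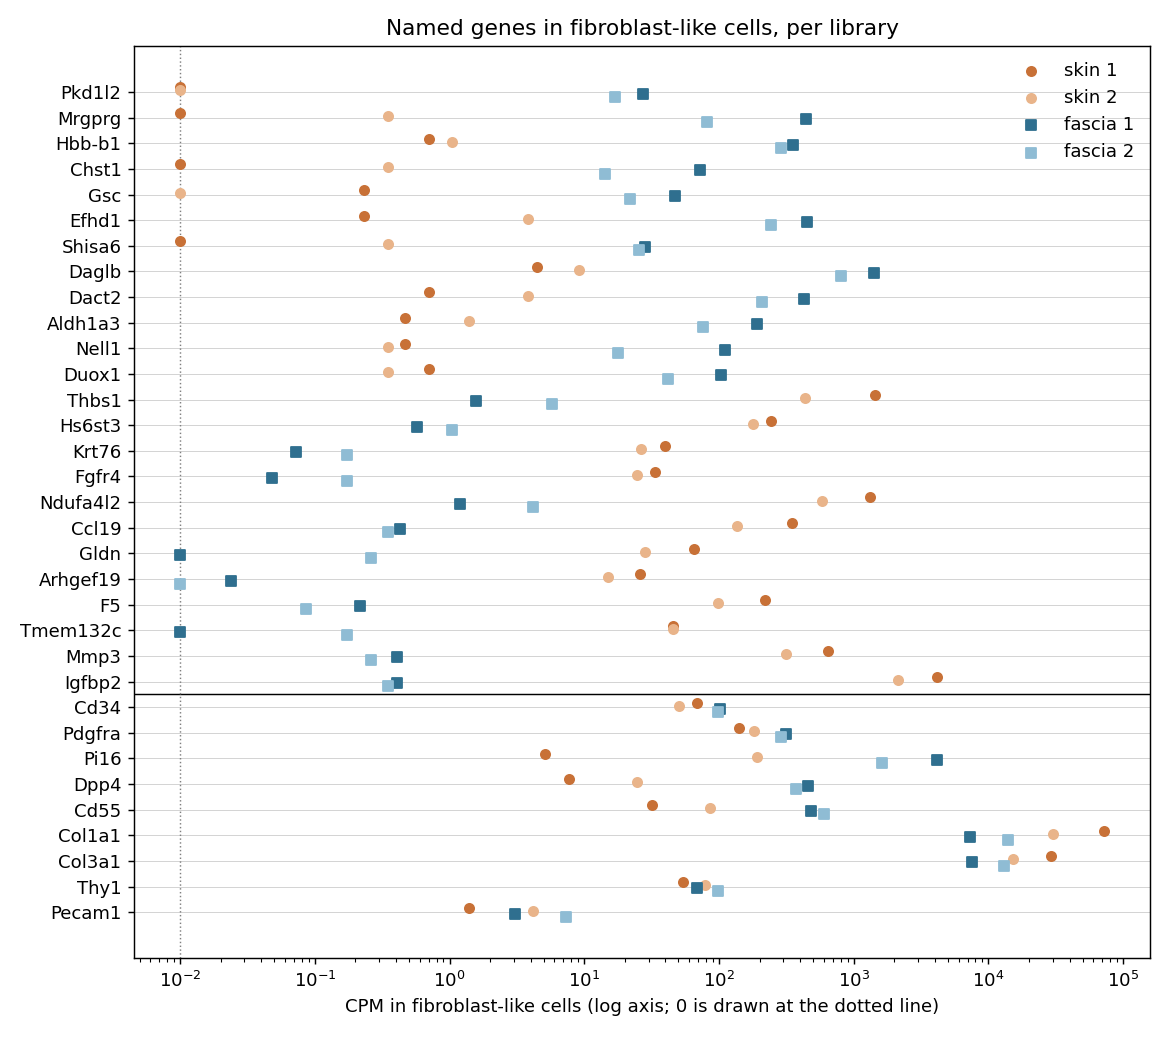
CPM (log axis) of named genes in fibroblast-like cells, with 1 point per library. The upper block holds the 12 genes with the largest change in each direction, such as Igfbp2 at 4160 and 2140 CPM in skin and 0.407 and 0.346 in fascia, and the lower block the genes named beforehand.

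The series title names CD34-positive cells of the fascia, and Cd34, the gene of this sialomucin of endothelial and stromal progenitor cells, was compared within fibroblasts. It was at 68.6 and 50.5 CPM in skin and 102 and 98 in fascia, a log2 change of 0.35 (SE 0.29, adjusted p = 0.46). With cells thinned to 2000 UMIs, 12.18% (8.76 to 16.33) and 10.42% (7.55 to 13.91) of skin and 17.7% (16.24 to 19.24) and 14.63% (12.1 to 17.46) of fascia fibroblasts had a Cd34 UMI. Lymphocytes, which should lack it, gave 0 of 74 and 1.71% (0.21 to 6.04) in skin and 0 of 310 and 0 of 757 in fascia. Their median depth before thinning was 4306, 3717, 8458 and 7038 UMIs, where the fibroblasts of the 4 libraries had 12647, 6185, 16897 and 16408.5. The log2 change was 0.81 and -0.0033 without skin replicates 1 and 2. It was 1.16 at Leiden resolution 0.5, 0.75 at 2.0 and 1.26 with mixed clusters, none called. With 4.5% of simulated 2-fold changes found, a difference stays open.

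Across classes, Cd34 was highest in fibroblasts, followed by blood endothelial cells, where 9.86% (5.5 to 15.99) and 8.2% (5.15 to 12.27) of skin cells and 8.01% (5.93 to 10.54) and 10.1% (8.27 to 12.19) of fascia cells had a UMI at 2000 UMIs per cell. The endothelial level was 44.6 and 40.6 CPM in skin and 50.1 and 57.5 CPM in fascia, with a log2 change of -0.13 (SE 0.23, adjusted p = 0.69). This has the other sign because the test scales the libraries by TMM, which makes the levels 58.9 and 42.9 in skin and 41.3 and 50.8 in fascia. Lymphatic endothelial cells of skin gave 3.37% (0.7 to 9.54) and 4.74% (2.39 to 8.33). Mural cells gave 0 of 74 and 0 of 269 in skin, which allow shares of cells with a UMI of up to 4.05% and 1.11%, and 0.24% (0.05 to 0.7) and 0.05% (0 to 0.29) in fascia. Macrophages gave 0 of 42 and 0 of 24 in skin and 0.79% (0.4 to 1.41) and 0.29% (0.08 to 0.75) in fascia, where the lymphocytes allow up to 0.968% and 0.396%, so these shares do not part macrophages from background. At full depth Cd34 was at 2.94 and 1.29 CPM in fascia macrophages and 0.71 and 0.17 in lymphocytes. Skin keratinocytes, a class in which hair follicle bulge cells can express Cd34, gave 1.93% (1.58 to 2.32) and 1.25% (0.98 to 1.57). Dendritic cells had no such cell in any library. No test was run between classes.

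**Figure D3:**
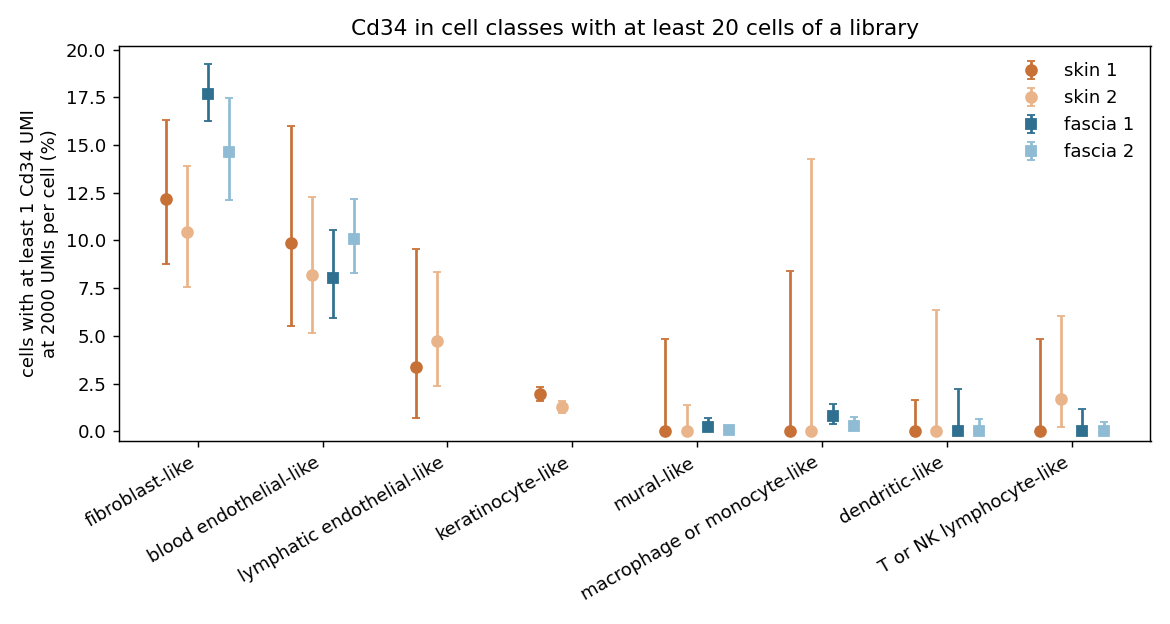
Share of cells (%) with at least 1 Cd34 UMI after thinning each cell to 2000 UMIs, by class and library, with exact 95% binomial intervals. Fascia fibroblasts reach 17.7% and 14.63% and skin keratinocytes 1.93% and 1.25%.

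Fibroblasts with a Cd34 UMI were compared with those without, at equal depth and with library as a block, to ask which genes accompany Cd34. Cells with Cd34 had less of the chemokine gene Cxcl14, at log2 -1.87 (SE 0.20, adjusted p = 2.5e-09). Stmn2 (-1.82, SE 0.21, adjusted p = 1.9e-08), Nr2f2 (-1.65, SE 0.31, adjusted p = 0.00047), a nuclear receptor gene, Arhgdib (-1.94, SE 0.30, adjusted p = 2.2e-05), Myo1d (-2.0, SE 0.49, adjusted p = 0.014), Ing1 (-1.78, SE 0.45, adjusted p = 0.021) and Wfdc1 (-1.67, SE 0.37, adjusted p = 0.0045) were lower in 4 of 4 libraries as well. Higher in 4 of 4 libraries were the integrin gene Itgb3 at 0.89 (SE 0.22, adjusted p = 0.017), Antxr1 at 0.66 (SE 0.17, adjusted p = 0.025), the TGF-beta coreceptor gene Tgfbr3 at 0.55 (SE 0.14, adjusted p = 0.029) and Pi16 at 0.48 (SE 0.13, adjusted p = 0.045). Phactr1 (0.62, SE 0.17, adjusted p = 0.031), Arhgef12 (0.62, SE 0.17, adjusted p = 0.03) and the bicarbonate transporter gene Slc4a4 (0.56, SE 0.15, adjusted p = 0.036) were higher too. Itgb3 turned to -0.07 at 1000 UMIs per cell and Tgfbr3 to -0.08 with at least 2 UMIs. In all, 12 genes were higher and 97 lower of 6845 tested. The total of 109 became 13 without fascia replicate 1, 44 without fascia replicate 2 and 166 without skin replicate 2, and 2 with each cluster of each library as its own block. At 2000 UMIs, cells with Cd34 were 21.14% and 19.19% of cluster 2 but 6.75% and 5.88% of cluster 11 in fascia. DESeq2 called 5 genes, and edgeR 30 at 1000 and 188 at 4000 UMIs per cell and 11 with at least 2 UMIs.

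Blood endothelial-like cells of skin expressed cytokine and adhesion genes that were lower in fascia. Csf3, the granulocyte growth factor gene, was at 3110 and 1220 CPM in skin and 0 and 0.538 CPM in fascia, a log2 change of -13.19 (SE 1.13, adjusted p = 0.003). The cytokine gene Il6 was at 1470 and 1290 CPM in skin and 2.53 and 3.61 CPM in fascia, a change of -9.27 (SE 0.46, adjusted p = 0.001). Olr1 was at -8.90 (SE 0.69, adjusted p = 0.0023). Fgf23, at 53.5 and 35.8 CPM in skin, had no UMI in fascia and was at least 323-fold lower. Selp and Icam1, adhesion molecule genes of activated endothelium, were at -5.44 (SE 0.46, adjusted p = 0.003) and -5.29 (SE 0.36, adjusted p = 0.0023). Higher in fascia were Hbb-b1 (7.88, SE 0.67, adjusted p = 0.003), Hba-a2 (6.79, SE 0.68, adjusted p = 0.0036) and Esm1, a gene of tip cells (5.73, SE 1.17, adjusted p = 0.022). In fascia, 1% of the endothelial cells held 96.2% and 93.1% of the haemoglobin UMIs. Cacng3 had no UMI in skin and was at least 52.3-fold higher. Nwd2 and Tesc had 1 UMI in skin, with ratios of 115 (counting interval 20.6 to 4560) and 75.3 (counting interval 13.4 to 2980). Scd, with 1 UMI in fascia, had a skin-to-fascia ratio of 836 (counting interval 148 to 33200).

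Among the lists in blood endothelial cells, several inflammatory and stress genes were lower in fascia. The cytokine and chemokine list had 1 higher, 14 lower and 3 not called of 18 tested (2 and 14 within the list), camera adjusted p = 4.42e-17, or 0.51 with an estimated correlation. The immediate early and heat shock list had 1 higher, 11 lower and 10 not called of 22 tested (1 and 17 within the list), camera adjusted p = 4.13e-09, or 0.51 with an estimated correlation. Atf3 was at -3.18 (SE 0.30, adjusted p = 0.0034) and the chaperone gene Hspa8 at -2.95 (SE 0.51, adjusted p = 0.014). The hypoxia and glycolysis list had 0 higher, 5 lower and 9 not called of 14 tested (0 and 6 within the list), camera adjusted p = 0.00184, or 0.51 with an estimated correlation. Slc2a1 was at -2.81 (SE 0.21, adjusted p = 0.0023) and the vasodilator peptide gene Adm at -2.15 (SE 0.56, adjusted p = 0.043). The proliferation list had 0 higher, 5 lower and 14 not called of 19 tested (0 and 5 within the list), camera adjusted p = 0.00555, or 0.538 with an estimated correlation. The cytokinesis gene Prc1 was at -2.42 (SE 0.41, adjusted p = 0.013) and the replication gene Mcm4 at -2.01 (SE 0.27, adjusted p = 0.0076). The axon guidance and neurotrophin list had 0 higher, 5 lower and 10 not called of 15 tested (0 and 6 within the list), camera adjusted p = 0.0139, or 0.538 with an estimated correlation. The neurotrophin gene Bdnf had 1 UMI in fascia and a ratio of 406 (counting interval 70.5 to 16300), and Sema3e was at -7.98 (SE 0.82, adjusted p = 0.0038). The endothelial subtype list had 3 higher, 5 lower and 10 not called of 18 tested (8 and 5 within the list), camera adjusted p = 0.491, or 0.676 with an estimated correlation. Its median and mean were above 0 and its test below.

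Lists of other cell types were called in blood endothelial cells too. The MHC class II list had 2 higher, 0 lower and 4 not called of 6 tested (5 and 0 within the list), camera adjusted p = 0.00555, or 0.538 with an estimated correlation. The resident macrophage list had 5 higher, 0 lower and 7 not called of 12 tested (6 and 0 within the list), camera adjusted p = 0.00555, or 0.51 with an estimated correlation. The epidermal transcript list had 0 higher, 11 lower and 0 not called of 11 tested (0 and 11 within the list), camera adjusted p = 4.11e-13, or 0.51 with an estimated correlation. Of their members, 6 of 6, 11 of 12 and 11 of 11 were under 0.2 of the level in the highest class. Cd74 was at 3.29 (SE 0.75, adjusted p = 0.029), RT1-Da at 3.09 (SE 0.70, adjusted p = 0.029). Fcna was at 0 and 0 CPM in skin and 16.2 and 6.61 CPM in fascia, Lyve1 at 0 and 0 CPM in skin and 8.4 and 4.15 CPM in fascia, and the keratin genes Krt17 and Krt15 at 154 and 390 and 432 and 2570 CPM in skin. Epidermal transcripts were 0.099% and 0.716% of UMIs in skin replicates 1 and 2 against 0.002% and 0.002% in fascia. Of 12016 genes tested, 936 were higher and 1483 lower in fascia (by DESeq2 621 and 1601), and the total of 2419 became 900 without fascia replicate 1 and 1197 without fascia replicate 2. Cluster 21, led by Csf3, Selp, Sele and Il6, held 77.6% and 95.4% of skin endothelial cells, and cluster 8 held 79.5% and 74.4% of those of fascia. Without skin replicate 1, the calls were lost for Esm1, Cacng3, Tesc, Adm, Cd74 and RT1-Da. With skin replicate 2 left out, the calls were lost for Cacng3, Tesc (adjusted p = 0.051), Adm and Lyve1. Without fascia replicate 1, the calls were lost for Tesc, Hspa8 and Fcna, and Adm moved to -3.34. With fascia replicate 2 left out, the calls were lost for Hspa8 and Lyve1, and RT1-Da moved to 1.96. Camera's adjusted p without skin replicate 2 was 0.13 for the proliferation and 0.11 for the axon guidance list.

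Mural-like cells were compared in the same way. Skin mural cells expressed Msx2 and Irx1, homeobox genes, with log2 changes of -7.89 (SE 0.50, adjusted p = 0.00013) and -7.61 (SE 0.48, adjusted p = 0.00013). Sphk1, a sphingosine kinase gene, was at -7.39 (SE 0.28, adjusted p = 3.4e-05), the protease inhibitor gene Tfpi2 at -7.37 (SE 0.34, adjusted p = 8.2e-05) and Kctd16 at -9.88 (SE 0.85, adjusted p = 0.0004). Fascia mural cells expressed Aldh1a2 at 25.5 and 60.1 CPM with no UMI in skin, at least 27.1-fold higher. Slc35f3 (at least 14.8-fold) and Ptchd4 (at least 14.2-fold) had no UMI in skin either. Hba-a2 was at 4.26 and 2.1 CPM in skin and 24.8 and 1070 CPM in fascia, a change of 7.23 (SE 2.03, adjusted p = 0.046). In fascia, 1% of the cells held 8.8% and 93.6% of haemoglobin UMIs.

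Of the lists in mural cells, those for stress and inflammation were lower in fascia. The immediate early and heat shock list had 0 higher, 15 lower and 7 not called of 22 tested (0 and 17 within the list), camera adjusted p = 1.11e-08, or 0.617 with an estimated correlation. Ier3 was at -3.88 (SE 0.34, adjusted p = 0.00045) and Klf4 at -3.07 (SE 0.40, adjusted p = 0.002). The cytokine and chemokine list had 2 higher, 12 lower and 7 not called of 21 tested (2 and 14 within the list), camera adjusted p = 5.25e-08, or 0.564 with an estimated correlation. The cytokine gene Lif had 2 UMIs in fascia and a ratio of 130 (counting interval 29.8 to 1180), and Cxcl14 was at -7.24 (SE 0.62, adjusted p = 0.0004). The hypoxia and glycolysis list had 0 higher, 5 lower and 8 not called of 13 tested (1 and 5 within the list), camera adjusted p = 0.0077, or 0.63 with an estimated correlation. The hexokinase gene Hk2 was at -3.85 (SE 0.25, adjusted p = 0.00013) and Ldha at -1.11 (SE 0.21, adjusted p = 0.011). The angiogenic and growth factor list had 2 higher, 8 lower and 9 not called of 19 tested (4 and 8 within the list), camera adjusted p = 0.0292, or 0.605 with an estimated correlation. Fgf2 was at -3.29 (SE 0.25, adjusted p = 0.00023) and Nrg1 at -3.12 (SE 0.70, adjusted p = 0.022). The axon guidance and neurotrophin list had 1 higher, 5 lower and 9 not called of 15 tested (3 and 6 within the list), camera adjusted p = 0.0422, or 0.564 with an estimated correlation. Efna5, an ephrin gene, was at -6.25 (SE 1.12, adjusted p = 0.0085). The proteoglycan and hyaluronan list had 1 higher, 5 lower and 8 not called of 14 tested (2 and 5 within the list), camera adjusted p = 0.0111, or 0.655 with an estimated correlation. The hyaluronan synthase gene Has1 was at -5.46 (SE 0.31, adjusted p = 9.0e-05) and the proteoglycan gene Lum at -3.63 (SE 0.82, adjusted p = 0.022).

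Fibrillar collagen and complement lists were higher in fascia mural cells by camera. The fibrillar collagen and collagen processing list had 6 higher, 1 lower and 16 not called of 23 tested (11 and 2 within the list), camera adjusted p = 0.0292, or 0.564 with an estimated correlation. Loxl2 was at 2.08 (SE 0.24, adjusted p = 0.0013) and Pcolce at 1.93 (SE 0.22, adjusted p = 0.0013). The lower dermis list had 4 higher, 0 lower and 7 not called of 11 tested (4 and 1 within the list), camera adjusted p = 0.0272, or 0.564 with an estimated correlation. Inmt was at 2.72 (SE 0.47, adjusted p = 0.0071) and Cxcl12 at 2.49 (SE 0.38, adjusted p = 0.0042). The complement list had 5 higher, 0 lower and 6 not called of 11 tested (5 and 2 within the list), camera adjusted p = 0.00718, or 0.564 with an estimated correlation. Cfd had 2 UMIs in skin, none of them in replicate 1, and a ratio of 35.6 (counting interval 9.85 to 295), and Cfb was at 3.20 (SE 0.34, adjusted p = 0.00093). The interferon response list had 4 higher, 2 lower and 8 not called of 14 tested (6 and 2 within the list), camera adjusted p = 0.034, or 0.689 with an estimated correlation. Gbp2 was at 3.10 (SE 0.57, adjusted p = 0.0093) and Cxcl10 at -3.47 (SE 0.51, adjusted p = 0.0037). The resident macrophage list had 4 higher, 0 lower and 8 not called of 12 tested (7 and 1 within the list), camera adjusted p = 0.0111, or 0.617 with an estimated correlation. The epidermal transcript list had 0 higher, 9 lower and 1 not called of 10 tested (0 and 9 within the list), camera adjusted p = 4.05e-34, or 0.152 with an estimated correlation. All macrophage and epidermal members were under 0.2 of the level in the highest class. So were 9 collagen, 5 lower dermis, 7 complement and 6 interferon members. Pf4 and Ccl24 were at 0 CPM in skin and 8.83 and 9.2 and 5.01 and 6.36 CPM in fascia. The keratinocyte genes Krt17 and Dsp were at 66 and 46.2 and 25.6 and 14 CPM in skin. Epidermal transcripts were 0.09% and 0.049% of UMIs in skin replicates 1 and 2 against 0.001% and 0.001% in fascia.

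In mural cells 789 genes were higher and 1318 lower in fascia of 12561 tested, and the total of 2107 became 679 and 697 without fascia replicates 1 and 2. Cluster 26, led by Xirp1, Avpr1a and Adamts4, held 62.3% and 87.9% of skin mural cells, and clusters 4 and 9 nearly all of those of fascia. Within cluster 9, which all libraries fill, 70 genes were called, 3 higher and 67 lower in fascia of 10539 tested, where Pcolce was at -0.07 and Fgf2 at 1.04 on the log2 scale, neither called. Without skin replicate 1, the call was lost for Hba-a2. With skin replicate 2 left out, the calls were lost for Aldh1a2, Ptchd4, Hba-a2, Nrg1 (-1.54), Lum, Pf4 and Ccl24, and Inmt and Gbp2 had no UMI in the other skin library and Cxcl10 moved to -2.11. Without fascia replicate 1, the calls were lost for Lif, Ldha, Nrg1, Efna5 and Pf4. With fascia replicate 2 left out, the calls were lost for Lif, Ldha, Nrg1, Efna5, Lum and Pf4, and Hba-a2 moved to 2.75. Camera's adjusted p was 0.11, 0.071 and 0.059 for the lower dermis and 0.52, 0.11 and 0.26 for the interferon list without skin replicate 1, skin replicate 2 and fascia replicate 1. It was 0.16 for the axon guidance list without skin replicate 1. Without skin replicate 2 and fascia replicate 2 it was 0.16 and 0.077 for the proteoglycan, 0.21 and 0.074 for the angiogenic and 0.071 and 0.077 for the hypoxia list.

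Macrophage- or monocyte-like cells were rare in skin, with 45 and 29 cells against 1406 and 1391 in fascia. Skin macrophages expressed the chemokine gene Ccl4 at 3320 and 1300 CPM in skin and 12.7 and 22.3 CPM in fascia, a log2 change of -7.30 (SE 0.65, adjusted p = 0.00037). Ahrr was at -8.31 (SE 0.56, adjusted p = 8.3e-05). Sphk1 (-7.19, SE 0.70, adjusted p = 0.00057), Adm (-6.78, SE 0.59, adjusted p = 0.00036) and the placental growth factor gene Pgf (-6.69, SE 0.85, adjusted p = 0.0021) were lower in fascia too. Fascia macrophages expressed Slpi at 2480 and 713 CPM with no UMI in skin, at least 302-fold higher. Cd209f (at least 60.7-fold), Cd226 (at least 25.3-fold), Hba-a3 (at least 18.4-fold) and Bank1 (at least 8.86-fold) had no UMI in skin either. In fascia, 1% of the cells held 60% and 11.7% of haemoglobin UMIs.

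Of the lists fixed for macrophages, the resident one was higher in fascia. The resident macrophage list had 3 higher, 0 lower and 10 not called of 13 tested (7 and 2 within the list), camera adjusted p = 0.0171, or 0.625 with an estimated correlation. Lyve1, a hyaluronan receptor gene of perivascular macrophages, was at 4.30 (SE 0.68, adjusted p = 0.006) and Fcna at 2.27 (SE 0.33, adjusted p = 0.0041). The lipid-associated macrophage list had 1 higher, 5 lower and 5 not called of 11 tested (1 and 6 within the list), camera adjusted p = 0.00198, or 0.299 with an estimated correlation. The tetraspanin gene Cd9 was at -4.43 (SE 0.63, adjusted p = 0.0037) and the galectin gene Lgals3 at -3.27 (SE 0.61, adjusted p = 0.012). The MHC class II list had 1 higher, 0 lower and 8 not called of 9 tested (3 and 0 within the list), camera adjusted p = 0.00281, or 0.625 with an estimated correlation. RT1-DOa was at 2.37 (SE 0.57, adjusted p = 0.037). The immediate early and heat shock list had 0 higher, 18 lower and 4 not called of 22 tested (0 and 18 within the list), camera adjusted p = 7.93e-22, or 0.256 with an estimated correlation. Hspb1 was at -5.21 (SE 0.37, adjusted p = 0.00011) and Hsp90aa1 at -3.95 (SE 0.34, adjusted p = 0.00034). The cytokine and chemokine list had 1 higher, 8 lower and 10 not called of 19 tested (3 and 9 within the list), camera adjusted p = 6.79e-06, or 0.256 with an estimated correlation. The prostaglandin synthesis gene Ptgs2 was at -6.88 (SE 0.71, adjusted p = 0.00078) and Cxcl3 at -6.27 (SE 1.55, adjusted p = 0.041). The hypoxia and glycolysis list had 0 higher, 4 lower and 9 not called of 13 tested (0 and 4 within the list), camera adjusted p = 2.55e-06, or 0.256 with an estimated correlation. Adm and the angiogenic factor gene Vegfa at -4.48 (SE 0.60, adjusted p = 0.0028) were the largest changes in it.

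Lists not fixed for macrophages passed as well. The angiogenic and growth factor list had 0 higher, 4 lower and 9 not called of 13 tested (0 and 5 within the list), camera adjusted p = 2.31e-05, or 0.256 with an estimated correlation. Pgf and Nrg1 at -6.43 (SE 1.08, adjusted p = 0.0082) led it. The axon guidance and neurotrophin list had 1 higher, 3 lower and 4 not called of 8 tested (1 and 4 within the list), camera adjusted p = 0.000808, or 0.256 with an estimated correlation. Sema3e had no UMI in fascia (at least 380-fold lower), and Slit2 was at -4.46 (SE 0.88, adjusted p = 0.016). The adipogenic list had 1 higher, 3 lower and 6 not called of 10 tested (1 and 5 within the list), camera adjusted p = 0.00534, or 0.257 with an estimated correlation. Plin2 was at -3.79 (SE 0.34, adjusted p = 0.00037) and Fabp4 at -3.26 (SE 0.46, adjusted p = 0.0035). The endothelial subtype list had 0 higher, 2 lower and 6 not called of 8 tested (0 and 2 within the list), camera adjusted p = 0.00255, or 0.256 with an estimated correlation. Rgcc was at -3.96 (SE 0.39, adjusted p = 0.00063). The upper dermis and dermal papilla list had 0 higher, 2 lower and 9 not called of 11 tested (0 and 3 within the list), camera adjusted p = 0.0171, or 0.473 with an estimated correlation. Sfrp1 was at -5.32 (SE 0.86, adjusted p = 0.0066) and Prdm1 at -4.32 (SE 0.76, adjusted p = 0.0098). The epidermal transcript list had 0 higher, 7 lower and 1 not called of 8 tested (0 and 8 within the list), camera adjusted p = 1.99e-36, or 0.256 with an estimated correlation. Its 8 members were under 0.2 of the keratinocyte level, with Krt15 at 298 and 757 and Lgals7 at 198 and 378 CPM in skin. Epidermal transcripts were 0.085% and 0.225% of UMIs in skin replicates 1 and 2 against 0.002% and 0.001% in fascia.

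In macrophages or monocytes 266 genes were higher and 563 lower in fascia of 11766 tested. The total of 829 became 93 without skin replicate 1, 356 without fascia replicate 1 and 516 without fascia replicate 2. The median log2 change over all tested genes was 0.24, and 0.15 with size factors by relative log expression. Cluster 12 held 97.8% and 96.6% of skin macrophages and 27.5% and 45.2% of those of fascia. Other fascia macrophages lay in cluster 15, led by Lyz2 and Ccr2, and cluster 17, led by Slpi and Fcna. Within cluster 12 alone 1171 genes were called. Cxcl3 and Slit2 did not separate the libraries of the tissues. Without skin replicate 1, the calls were lost for Sphk1, Adm, Slpi, Cd209f, Hba-a3, Bank1, Lyve1, Lgals3 (-1.76), RT1-DOa, Ptgs2 (-3.77), Cxcl3 (0.51), Vegfa (-2.56), Nrg1, Slit2 (adjusted p = 0.81), Fabp4 (-1.95), Rgcc, Sfrp1 and Prdm1. With skin replicate 2 left out, the calls were lost for Bank1, RT1-DOa and Nrg1. Without fascia replicate 1, the calls were lost for Bank1, RT1-DOa, Sema3e and Slit2. With fascia replicate 2 left out, the calls were lost for RT1-DOa and Slit2. Camera's adjusted p was 0.48 and 0.052 for the axon guidance list without skin replicate 1 and fascia replicate 2, 0.079 and 0.065 for the resident list without skin replicate 2 and fascia replicate 1, 0.098 for MHC class II without skin replicate 1 and 0.2 for the upper dermis list without skin replicate 2.

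T- or NK-like lymphocytes of fascia had higher levels of several genes of cell division. Aurkb, a mitotic kinase gene, had no UMI in skin lymphocytes and 18.7 and 12.8 CPM in fascia, at least 5.37-fold higher. The spindle gene Tpx2 had 2 UMIs in skin, none of them in replicate 1, and a ratio of 13.5 (counting interval 3.69 to 112). The chemokine receptor gene Ccr2 was at 4.15 (SE 0.38, adjusted p = 5.0e-05). Nkain2 (at least 14-fold), Slit2 (at least 9.61-fold), Wdr95 (at least 9.07-fold) and the NK receptor gene Klra17 (at least 7.66-fold) had no UMI in skin. Skin lymphocytes expressed Gzmf, a granzyme gene, at 482 and 162 CPM, 2520 (counting interval 448 to 99700) times the fascia level, and Ahrr at -9.30 (SE 0.81, adjusted p = 3.7e-05). Homer2 (at least 260-fold) and Ccdc60 (at least 114-fold) had no UMI in fascia, and Krt79 had 1, with a ratio of 1190 (counting interval 210 to 47200).

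The lists in lymphocytes moved both ways. The proliferation list had 12 higher, 0 lower and 8 not called of 20 tested (12 and 0 within the list), camera adjusted p = 2.04e-05, or 0.562 with an estimated correlation. The inflammatory monocyte list had 4 higher, 1 lower and 4 not called of 9 tested (4 and 1 within the list), camera adjusted p = 0.0211, or 0.796 with an estimated correlation. Ccr2 was among its higher members. The immediate early and heat shock list had 0 higher, 9 lower and 13 not called of 22 tested (0 and 9 within the list), camera adjusted p = 2.04e-05, or 0.796 with an estimated correlation. Atf3 was at -3.91 (SE 0.33, adjusted p = 3.2e-05) and Hspb1 at -3.86 (SE 0.28, adjusted p = 1.4e-05), for which keratinocyte RNA at the Krt15 level of these cells would give 0.547 and 1.14 of the skin CPM. The hypoxia and glycolysis list had 0 higher, 5 lower and 8 not called of 13 tested (0 and 5 within the list), camera adjusted p = 0.0058, or 0.679 with an estimated correlation. Vegfa was at -3.61 (SE 0.78, adjusted p = 0.0097) and Ndrg1 at -3.02 (SE 0.31, adjusted p = 0.0001). The lipid-associated macrophage list had 0 higher, 5 lower and 4 not called of 9 tested (0 and 5 within the list), camera adjusted p = 0.014, or 0.679 with an estimated correlation. The macrophage genes Gpnmb and Apoe were at -3.59 (SE 0.79, adjusted p = 0.01) and -3.0 (SE 0.46, adjusted p = 0.0013), and 7 of its 9 members were under 0.2 of the level in the highest class. The epidermal transcript list had 0 higher, 10 lower and 0 not called of 10 tested (0 and 10 within the list), camera adjusted p = 2.22e-25, or 0.562 with an estimated correlation. Krt17 had 2 UMIs in fascia and a ratio of 2200 (counting interval 605 to 18200), Krt15 was at -9.72 (SE 0.53, adjusted p = 5.1e-06), and epidermal transcripts were 0.21% and 0.551% of UMIs in skin replicates 1 and 2 against 0.002% and 0.004% in fascia. Of 9842 genes tested, 824 were higher and 1109 lower in fascia, a total of 1933 that became 383 without fascia replicate 1 and 797 without fascia replicate 2. Cluster 35, led by Trat1 and Gzmf, held 48.9% and 25.9% of skin lymphocytes and none of the fascia ones. Within cluster 18, which all libraries fill, 858 genes were called. With skin replicate 2 left out, Apoe moved to -1.96 on the log2 scale. Without fascia replicate 1, the calls were lost for Tpx2, Wdr95 and Klra17, and Vegfa moved to -5.61. With fascia replicate 2 left out, the calls were lost for Aurkb, Tpx2 and Vegfa (-2.40). Camera's adjusted p was 0.063 for the hypoxia list without skin replicate 2 and 0.26 for the inflammatory monocyte list without skin replicate 1.

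In dendritic-like cells 1298 genes were higher and 1528 lower in fascia of 9570 tested. Cluster 30, led by the Langerhans cell gene Cd207, held 68.7% and 66.7% of skin dendritic cells, and cluster 16 held all of those of fascia. The total of 2826 became 717 within cluster 16 alone, 5230 without skin replicate 2, 1054 without fascia replicate 1 and 951 without fascia replicate 2. Their immediate early and heat shock list had 0 higher, 9 lower and 13 not called of 22 tested (0 and 9 within the list), camera adjusted p = 0.00718, or 0.77 with an estimated correlation. This camera call was lost without skin replicate 2 (adjusted p = 0.4). Cd34 was at 0 UMIs in 3 libraries and 2 UMIs in fascia replicate 1, too few for a test.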

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

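Chosen after the result was seen were the tests of free RNA, of the mix of clusters behind immediate early genes, of handling of the skin libraries and of other splits of the cell sums, the milk protein genes and the clusters as blocks of the Cd34 split. The tests of immediate early genes were first run on the called members alone and then reset to all members, and the upper quartile was added to the bound for free RNA after the lymphocyte value was seen, which by its median alone would have counted against free RNA there.

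For 49 genes the difference between fibroblasts with and without a Cd34 UMI itself differed between fascia and skin in edgeR's test of the interaction, 2 higher and 47 lower in fascia. Igfbp3 differed by -3.24 on the log2 scale between tissues. In cells without and with a Cd34 UMI among 2000 UMIs, Igfbp3 was at 295 and 40 CPM in fascia replicate 1 and 351 and 48.6 in fascia replicate 2. It was at 374 and 237 in skin replicate 1 (38 cells with Cd34) and 326 and 700 in skin replicate 2 (40). Igfbp7 differed by -1.84 and Crabp1 by -2.35, both lower with Cd34 in fascia. The share of cells with Cd34 was 21.14% and 19.19% in fascia cluster 2 and 6.75% and 5.88% in cluster 11. It was 10.04% to 11.8% in skin clusters. Whether their mix gives these differences was not tested.

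The genes that accompany Cd34 could follow the clusters rather than Cd34. With clusters of each library as blocks the median change of the 109 genes was 0.70 of its size, between the bounds set beforehand, so cluster and Cd34 cannot be told apart for them. Of 8 splits that part the 2 sums of each library, 1 gave as many genes, the real one, and the highest other gave 63, a number of splits too small for a share under 0.05. Splits that keep the 2 sums of a library together gave up to 118, the highest where the fascia libraries alone were parted by Cd34.

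The immediate early and heat shock list, with genes such as Atf3 and Hspb1, was lower in fascia in the 6 classes tested by camera (adjusted p = 0.00718 or less), with an adjusted p = 0.256 to 0.796 with an estimated correlation, and without skin replicate 2 its adjusted p in dendritic cells was 0.4. Free RNA from keratinocytes would give at most 0.12 of the skin level as the median of its members in a class, with upper quartiles of up to 0.23, which argues against it in classes other than lymphocytes. In lymphocytes this was 0.21, with an upper quartile of 0.36, 0.547 for Atf3 and 1.14 for Hspb1, and it stays open. Another mix of clusters is argued against in mural cells, macrophages, dendritic cells and lymphocytes, where the median log2 change of all 22 members within 1 shared cluster was 0.95 to 1.89 times that of the class, though in mural cells 1 of the 22 passed within it, against 15 in the class. In fibroblasts this median was -1.96, but only skin replicate 2 fills the shared cluster, and blood endothelial cells have none with 20 cells of every library. Handling of the skin libraries may have raised these genes, and with the list lower in fascia in 6 of 6 classes it cannot be told apart from a difference between the tissues.

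An unnamed cluster of fascia cells, cluster 28, with fibroblast as its best class, had Cd34 at 270 CPM in replicate 1 (213 cells) and 99 CPM in replicate 2 (22 cells), where fibroblast cluster 2 had 118.5 and 120.9 CPM. Its median depth was 3672 and 3062 UMIs, against 17775 and 17319.5 in cluster 2. Its ribosomal protein share of UMIs was 0.15 and 0.25 times that of cluster 2, as a loss of cytoplasm would give, but its mitochondrial share was 3.68 and 2.99 times that of cluster 2, which argues against a loss that took the mitochondria too. Its Cd34 level, from 250 and 9 UMIs, was 4.73 and 3.96 times that of all cells. As the cluster was chosen for this, free RNA stays open. Leaking cells that kept their mitochondria stay open. In cluster 2 cells richest in mitochondrial RNA had 1.52 and 0.90 times the Cd34 level of the others in replicates 1 and 2. No biological explanation was tested.

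Milk protein genes (Csn1s1, Csn2, Csn3 and Lalba) had 27830 UMIs in fascia replicate 2, against 20, 12 and 10 in skin replicates 1 and 2 and fascia replicate 1. In that library 27625 of them lay in keratinocyte-like cells, and 1 cell held 17508. No explanation was tested.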

How the results depend on the processing

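Keratinocytes left out of the total, mixed clusters named by their best class, 1 shared cluster alone, lists without free-RNA genes and clusters as blocks were tried after the results were seen. Of 3002 comparisons of a named gene with an alternative, 2689 kept direction and side of the threshold, 292 were weaker, 10 stronger and 11 reversed. For gene lists 243 of 332 were unchanged and 89 weaker, and for genes of the Cd34 split 64 of 134 were unchanged, 68 weaker and 2 reversed. Size factors by relative log expression left 193 of 194 named genes unchanged and DESeq2 189 of 193. The cause of each change below was not tested unless given.

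In fibroblasts, against 1318 called genes, DESeq2 called 2239, no low-count filter 3237, Leiden resolution 0.5 3350 and mixed clusters 2086. With no filter, 4272 were called in blood endothelial cells against 2419, 3241 in mural cells against 2107 and 1777 in macrophages against 829, where more genes were tested, and the share higher in fascia was 44.4% in fibroblasts against 30.5%, 51.5% in blood endothelial cells against 38.7% and 48.5% in mural cells against 37.4%. Within 1 shared cluster the calls were 70 in mural cells, 717 in dendritic cells and 858 in lymphocytes, but 1171 in macrophages, Fgf2 in mural cells was 1.04 and Pcolce -0.07. Thy1 in fibroblasts was 0.07 with no filter and 0.03 with doublets kept, against -0.01. With an estimated correlation 0 lists passed in fibroblasts, against 12, and 0 in blood endothelial cells, mural cells, macrophages and lymphocytes, against 38, and 20 passed in these once genes under 0.2 of the highest class were left out, which leaves fewer members. By fry, which tests for 1 direction and not against other genes, 4 of 139 lists passed, adipogenic and epidermal in mural and lower dermis and lipid-associated macrophage in blood endothelial cells, of which camera called the epidermal one.

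The log2 share ratio of fibroblasts was 1.90 at Leiden resolution 0.5, 2.46 at 2.0 and 0.80 with mixed clusters. That of blood endothelial cells was 2.19, 1.95 and 2.27 in the same order, and that of lymphocytes 2.78 and 2.24 at both resolutions. Mural cells gave 2.11 with mixed clusters. None of these passed the threshold, nor did B cells with -0.81 at resolution 2.0. At that resolution 6 classes passed against 10. Among the 6 was skeletal muscle (-7.62), a class that resolution 1.0 lacks, and neutrophils were not tested there. With keratinocytes left out of the total 1 class passed, and the ratios of the others were 0.60 for fibroblasts, 0.36 for blood endothelial, 2.12 for mural, 3.40 for macrophages, 0.79 for T or NK, 1.34 for B, -7.35 for mast, 2.74 for neutrophil and -0.78 for dendritic cells. The Cd34 split had 109 calls of 6845 tested, against 5 with DESeq2 and 30 at 1000 UMIs, where Itgb3 was -0.07. It had 188 at 4000 UMIs, 11 with at least 2 UMIs, where Tgfbr3 was -0.08, and 2 of 2242 tested with clusters as blocks.

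Leaving out each library in turn, where the lone library of a tissue is assumed to vary like the other tissue, gave 2947 to 4477 calls in all cells against 6749, 0 to 2633 in fibroblasts, 900 to 2611 in blood endothelial cells, 679 to 2908 in mural cells, 93 to 941 in macrophages, 951 to 5230 in dendritic cells, 383 to 2825 in lymphocytes and 13 to 166 in the Cd34 split. In fibroblasts the 0 calls of edgeR came without either fascia library, beside 1695 and 2214 genes at an unadjusted p under 0.05. Cd34 in fibroblasts was -0.0033 to 0.81, Thy1 -0.31 to 0.25, Pecam1 -0.14 to 1.31, Cd34 in blood endothelial cells -0.37 to 0.13, and in macrophages Cxcl3 was -7.26 to 0.51 and Slit2 -5.10 to 6.91 by a fit that has no skin UMI at the high end. The share ratios were 1.49 to 3.36 for fibroblasts, 1.81 to 2.59 for blood endothelial, 3.60 to 4.45 for mural, 2.07 to 3.34 for T or NK, 2.86 to 3.34 for B, -8.76 to -3.75 for mast and 2.46 to 5.89 for neutrophil cells, with 3 to 8 classes past the threshold.

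With the replicate number as a block, 781 genes were called in fibroblasts. The labels do not say that the numbers pair the libraries, and deviations of same-numbered libraries correlated across genes at -0.125 in all cells, 0.04 in fibroblasts and -0.165 in blood endothelial cells, so the numbers were not taken as pairs. Keratinocytes were not compared under any alternative, since fascia held 5 and 8, and no cluster was named dendritic at Leiden resolution 0.5.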

Other observations

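Haemoglobin transcripts were found across fascia classes. Hbb-b1 was at 1.01 and 2.79 CPM over all skin cells and 430 and 1140 CPM over all fascia cells, where 1% of the cells held 79.4% and 87.1% of them. In mural cells it was at 30.5 and 1500 CPM in fascia replicates 1 and 2, and in lymphocytes at 427 and 2420. The haemoglobin list fixed beforehand, without Hbb-b1 and with 3 of 6 genes in the table, was at 5.95 and 8.33 CPM in skin and 454 and 897 in fascia. The muscle list, with 9 of 10 genes in the table, was at 3.67 and 170 CPM in skin and 32.9 and 16.2 in fascia. Skeletal muscle cells formed a cluster, with Acta1 and Ckm among its leading genes, of 76 cells of skin replicate 2 at Leiden resolution 0.5 and 79 at 2.0, and none at 1.0. No cluster was named erythroid, Schwann, melanocyte, adipocyte or mesothelial at any of these resolutions. Names were given to whole clusters, so this sets no limit on the share of such cells, and small groups can lie within other clusters.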
